A study of Homo sapiens with 6 samples.

How the data were processed

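RNA of 6 mantle cell lymphoma lines was measured on 6 Agilent one-colour arrays, 1 per line. Per the labels, the lines were grown in RPMI-1640, RNA was taken with TRIZOL and 0.1 ug was labelled with Cy3. The tissue label reads whole blood for every sample, although the titles name cell lines. Per the file headers, the spot intensity was background-subtracted and detrended within each array by Feature Extraction 11.5.1.1 (10.7.3.1 per the labels) and not normalized between arrays. The flags deposited for each spot are other values, 0 or 1, that mark spots well above background, uneven or saturated. The deposited series table holds log2 values of the authors on an unstated centre. Its differences between lines correlated at 0.9983 to 0.9995 with those of quantile-normalized intensities (slopes 0.932 to 0.943). It was used for differences between lines.

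From the intensities, spots marked as outliers were dropped (between 238 and 366 per array), 902 probes spotted 10 times were averaged, and log2 signals were set relative to the 75th percentile of each array. No spot was saturated. A probe counted as above background when most of its spots were marked so, and a dim probe took its own value or the array floor (between -6.29 in Jeko-1 and -4.85 in Rec-1), whichever was higher. Folds against a dim probe are lower bounds, written "at least". Probes took current gene symbols through their transcript record (28170), their symbol (2621) or an older symbol (620), and 19188 kept the name in the file and were not used as genes. A gene took its probe with the highest mean, which gave 21361 genes, of which 18850 were above background on at least 1 array and 13600 on all. Of these genes, 7087 had more than 1 probe. For those with an SD over 1 across the lines, the median correlation over lines between probes was 0.915 (2017 pairs). Genes that varied less were not included in this value. The signal limited which genes could be read: JVM-13 had the lowest 75th percentile (452) and Rec-1 the fewest probes above background (27899). The 8 spiked-in control probes had a residual SD of 0.128 after the mean of each array was removed (0.181 for a difference), which leaves out error shared by an array. After scaling, their means ran from -0.75 in Jeko-1 to 1.15 in JVM-13, and their median SD over arrays was 0.73 (0.25 before scaling).

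Comparisons were counts of genes at least 4-fold (2 on the log2 scale) above or below all other lines, between 15 pairs of lines, and in both lines of a pair against the other 4. Lower genes had to be above background in the other lines. With 1 array per line no test between lines was possible. Genes were named by a rule: per line, the 5 largest measured gaps in each direction and every member of the gene lists at least 4-fold apart, likewise for the JVM pair and the pair sharing slide 1, and 20 fixed genes, of which 19 are reported. Uncharacterised loci, immunoglobulin and T cell receptor segments and the HLA-DQ, HLA-DRB3, HLA-DRB4 and HLA-DRB5 genes were not named. The examples given for each list were chosen after their values were seen.

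The 29 lists were the SOX11-associated signature, G1 cyclins with CDKs and inhibitors, proliferation, genes mutated in this lymphoma, BCL2 family and apoptosis inhibitors, B cell receptor signalling, canonical NF-kB targets, alternative NF-kB pathway, EBV-induced genes, germinal centre, plasma, mature and precursor B cell genes, MHC class I, MHC class II, interferon-stimulated genes, homing and adhesion, Notch targets, hypoxia and glycolysis, unfolded protein and amino acid response, growth arrest and DNA damage genes, MYC and nucleolar genes, heat shock and immediate early genes, therapy targets, cancer-testis antigens, and markers of T cells, myeloid cells, NK cells and erythroid and stromal cells. Each list's median was ranked among 10000 random lists matched in 20 bins of mean level (seed 1), and a list outside percentiles 2.5 to 97.5 stood apart. For the authors' values the mean was that of centred values, so matching there was not on expression level. The threshold, scaling, lists, naming rule and alternatives were fixed before the data were examined, except spike-in scaling.

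The alternatives were median scaling, quantile normalization, normexp background correction (offset 50) followed by quantile normalization, the authors' values, no filter, only genes above background on all arrays, the mean over probes, only the 4 lines of slide 2, leaving out each line, and spike-in scaling by 8 probes. The calculations were tested on simulated data. With 200 of 21361 genes changed in a line, 89.6% of 8-fold and 100.0% of 16-fold changes were called, 0.0% of 2-fold changes and 0 unchanged genes, and 5.5% of 600 unshifted list and line combinations stood apart. A list shifted 2-fold was recovered at 0.94. The simulated genes varied independently between lines (SD 0.4), shared a common floor and were changed only where bright. Real lines differ more and members of a list vary together, so these are not error rates for these arrays. The result for 2-fold changes follows from the 4-fold threshold. Python 3.11.15 (numpy 2.4.6, pandas 2.3.3, scipy 1.17.1, matplotlib 3.10.9) and R 4.3.3 with limma 3.58.1 were used. Genes tied to sex were left out by rule, and 6 list genes had no probe on the array.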

Results

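Gene expression was measured in 6 established cell lines of mantle cell lymphoma, a B cell lymphoma defined by cyclin D1 activation and marked in most cases by the transcription factor SOX11. The lines were Z-138, JVM-13, JVM-2, Mino, Jeko-1 and Rec-1. JVM-13 and JVM-2 were set up in culture with Epstein-Barr virus (EBV), which drives B cells to grow as lymphoblastoid cells. Total RNA of untreated cultures was labelled with Cy3 and hybridised to 1 Agilent array per line. There were no replicates, so differences between lines have no replicate error and no p-value, and genes are named by the size of the difference. The series describes a profile of each line, and the comparisons that follow set every line against the others.

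Between 27899 probes (55.1%, Rec-1) and 34958 probes (69.1%, Jeko-1) were well above background. The median SD of probes spotted repeatedly on an array was between 0.0567 and 0.0716 on the log2 scale, far below a 4-fold difference, but this covers spotting within an array and not a second culture. The 75th percentile of the signal ran from 452 in JVM-13 to 1123 in Jeko-1. Z-138 and Mino shared slide 1 and the other 4 lines shared slide 2, and each slide was scanned on its own, so slide and scan could not be separated. Levels below are log2 signals relative to the 75th percentile of the same array.

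Among 19 genes of interest in this lymphoma, SOX11 was well above background in Mino (4.25), Jeko-1 (4.22) and Rec-1 (1.65) and not in Z-138, JVM-13 or JVM-2. Its range over the lines was at least 1192-fold. The SOX11 probe lies on chromosome 2 at 5841428 to 5841487 (hg19, as are all coordinates here), in the 3′ part of the gene. CCND1, which encodes cyclin D1, was read by a single probe on chromosome 11 at 69468233 to 69468292, toward the 3′ end of the transcript. Its level was 1.82 in Mino, 1.59 in JVM-2, -1.28 in Z-138, -3.64 in Rec-1 and -5.88 in Jeko-1, and it was not well above background in JVM-13. CCND2, the cyclin D2 gene, was at 5.15 in Z-138, 4.21 in JVM-2 and 4.07 in JVM-13, at 1.33 in Mino and at -5.69 in Jeko-1, and was not well above background in Rec-1. CCND3 differed by no more than 2.25-fold across the lines.

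CXCR4, a chemokine receptor that guides B cells to bone marrow and lymph nodes, had a range of 2399-fold, from -4.25 in JVM-2 to 6.97 in Jeko-1. CD5, a surface marker of this lymphoma, was at 3.64 in Mino and 0.12 in Jeko-1, and not well above background in JVM-13 or Rec-1. JVM-13 thus had none of SOX11, CCND1 and CD5 well above background. CDKN2A, an inhibitor of CDK4 and CDK6, was at 6.63 in Mino, 5.20 in Jeko-1 and 1.02 in Rec-1, where its other probe was not well above background. PRDM1, a plasma cell regulator, ran from -2.58 in Jeko-1 to 2.83 in JVM-2. BCL6, the germinal centre repressor, was highest in Rec-1 (-1.33) and Jeko-1 (-1.83), and not well above background in Z-138 and JVM-13. BIRC3 ranged 19.9-fold, from 0.32 in Mino to 4.64 in Rec-1, and CD38 12.2-fold, with its maximum of 3.12 in JVM-2. ATM was highest in Jeko-1 (1.77), and BCL2 ran from 1.70 in Rec-1 to 3.73 in Mino. Several genes varied little by their brightest probe. The mean and SD over the 6 lines were 4.22 ± 0.27 for MS4A1 (CD20), 3.95 ± 0.42 for BTK, 1.83 ± 0.31 for MAP3K14, 0.28 ± 0.30 for NOTCH1, 2.30 ± 0.43 for MCL1 and 5.56 ± 0.58 for MYC (n = 6). A second, dimmer NOTCH1 probe varied more, from -4.58 in Jeko-1 to -0.25 in Mino, and a second MYC probe was not well above background in JVM-13 and JVM-2.

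**Figure D1:**
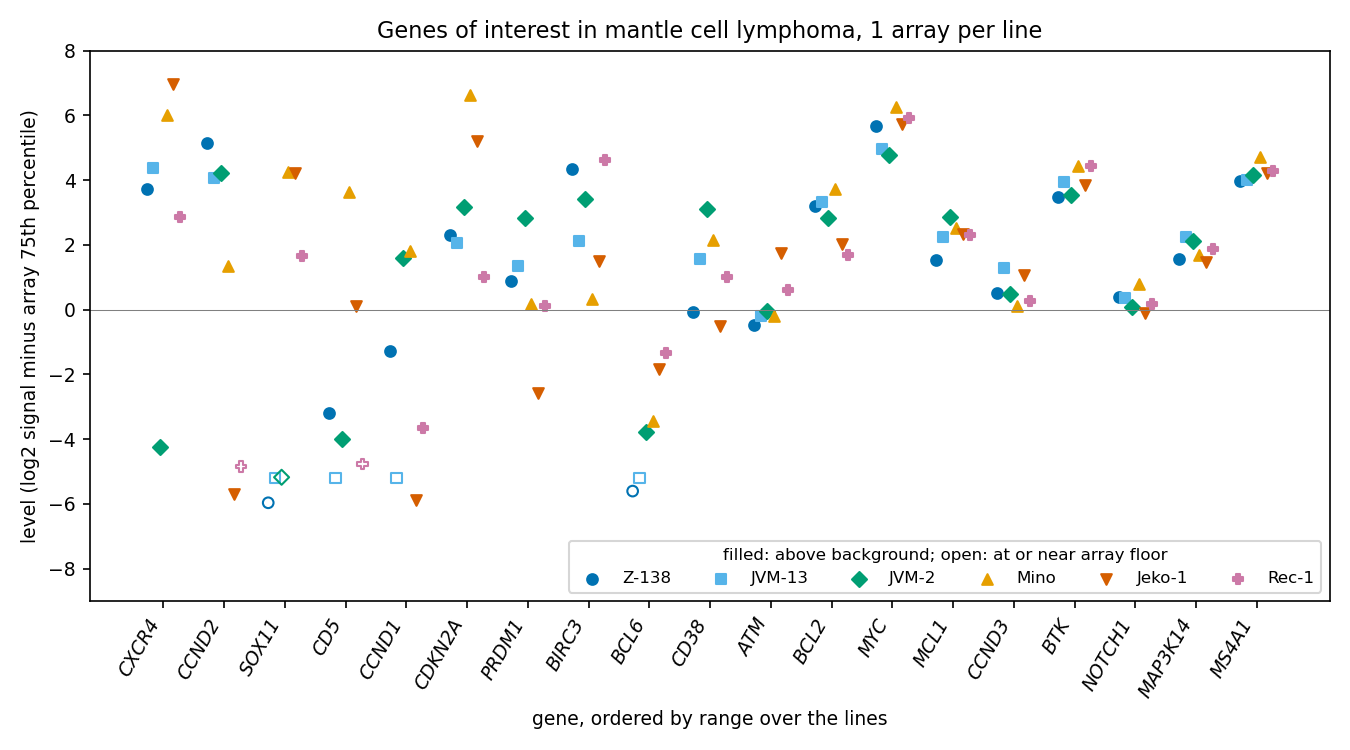
Levels of 19 genes in the 6 lines, as log2 signal minus the 75th percentile of the array, with 1 point per array and no error bars because each line has 1 array. Open points mark probes not well above background, and CXCR4 shows the widest range among genes above background in every line (11.23; the ranges of SOX11 and CCND2 are limited by the array floor), with JVM-2 far below the other lines.

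The lines were compared in pairs to see how alike they were. JVM-13 and JVM-2 were the closest, with 1276 genes at least 4-fold apart and a Pearson correlation of 0.947 (Spearman 0.944) across the 13600 genes well above background in all lines. Genes are not independent replicates, so these correlations carry no p-value. Z-138 was next to both of them, with 1384 genes apart from JVM-13 (r = 0.937) and 1606 from JVM-2 (r = 0.939), although it was on the other slide. Whether the Z-138 culture was the labelled line could not be checked from these data. Mino differed from Jeko-1 in 1927 genes (r = 0.906), from Rec-1 in 1996 (r = 0.906) and from Z-138, its partner on the slide, in 2282 (r = 0.889). Jeko-1 and Rec-1 were 2207 genes apart. JVM-13 and Jeko-1 were the farthest apart, with 3440 genes and r = 0.836. The remaining pairs had between 2379 and 3181 genes apart. Scaling to spiked-in controls, an alternative chosen after seeing the data, changed this order, with 2713 genes between JVM-13 and JVM-2 and 8599 between JVM-13 and Jeko-1.

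**Figure D2:**
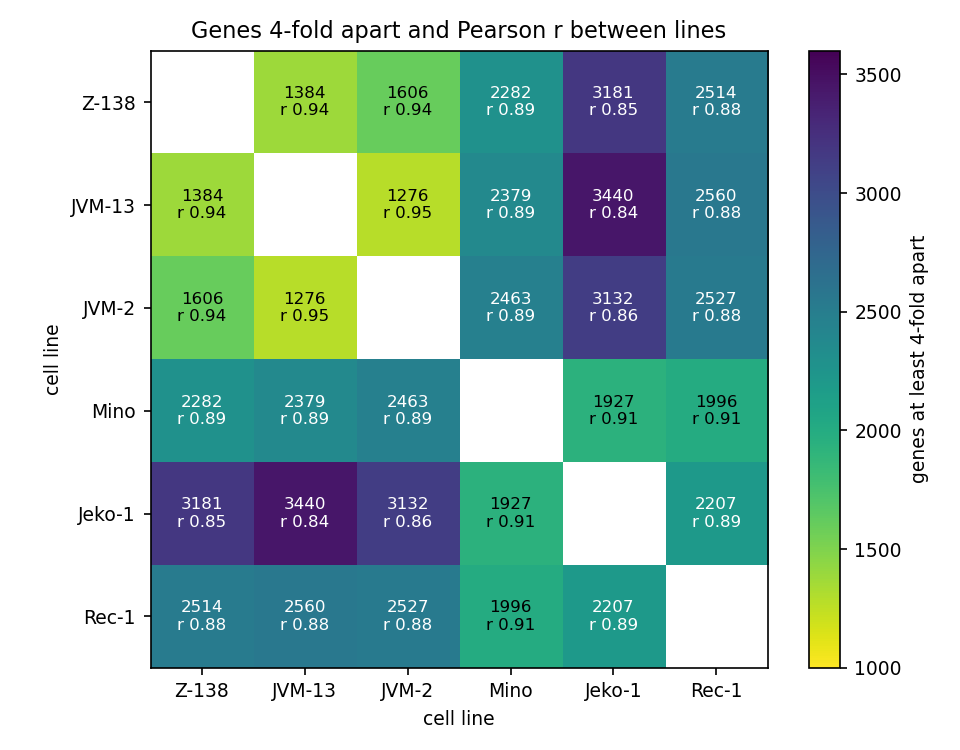
Each cell gives, for a pair of lines, the number of genes at least 4-fold apart (colour and upper figure) and the Pearson correlation across genes above background in all lines (lower figure), from 1 array per line. The smallest number is 1276 for JVM-13 and JVM-2 and the largest 3440 for JVM-13 and Jeko-1.

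Both JVM lines together exceeded the other 4 lines by at least 4-fold in 82 genes and fell below them in 20. The largest measured gaps were for EFR3B (16.8-fold), MOCOS (14.1-fold), PLEKHG3 (9.28-fold), BCAS3 (7.36-fold) and the chemokine CCL19 (7.05-fold). LTBR, the lymphotoxin beta receptor, was 4.95-fold higher. Lower in both were KATNAL2 (8.50-fold), MICOS10-NBL1 (8.35-fold), ISYNA1 (6.26-fold), CHST2 (6.03-fold), SLCO4A1 (5.82-fold) and the myeloid factor CEBPA (at least 4.21-fold). MICOS10-NBL1 is a readthrough transcript that shares sequence with its 2 parent genes. The pair on slide 1, Z-138 and Mino, gave 4 genes higher and 21 lower, the latter count no smaller than that of the JVM lines. Its largest gaps were for ASS1 (6.58-fold), IL32 (5.40-fold), FUT7 (4.28-fold), TNFRSF4 (3.67-fold) and TOX2 (3.49-fold) upward, and STAC3 (12.4-fold), TRO (4.70-fold), B4GALNT1 (4.69-fold), HOXC4 (4.61-fold), TUFT1 (4.11-fold) and IL7R (at least 7.07-fold) downward. Among the other 13 pairs, the highest counts were 88 higher (Jeko-1 and Rec-1) and 109 lower (Mino and Jeko-1). Within slide 2 alone, the JVM lines had 523 genes above and 320 below Jeko-1 and Rec-1. Averaging probes put EFR3B at 2.92-fold, BCAS3 (1 of 2 other probes opposed) at 2.03-fold and CHST2 at 3.92-fold. Under normexp LTBR was at 2.92-fold, CCL19 at 3.65-fold and CEBPA at 1.86-fold, and under spike-in scaling LTBR was at 2.99-fold, CCL19 at 2.21-fold and BCAS3 at 2.30-fold. For the slide 1 pair the lowest values under an alternative were 3.70-fold for FUT7, 1.99-fold for B4GALNT1, 2.00-fold for TRO, 2.13-fold for IL7R, 2.17-fold for HOXC4 and 2.78-fold for TUFT1.

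Each line was next set against the other 5. Genes at least 4-fold above the highest other line numbered 254 in Rec-1, 226 in Jeko-1, 219 in JVM-2, 129 in Z-138, 115 in JVM-13 and 84 in Mino. Genes at least 4-fold below the lowest other line numbered 169 in Jeko-1, 122 in Rec-1, 114 in Mino, 65 in Z-138, 56 in JVM-13 and 52 in JVM-2. These numbers depended on near neighbours. Without JVM-13 as a comparator, Z-138 had 239 higher and 122 lower and JVM-2 had 337 higher and 81 lower. Without JVM-2, JVM-13 had 232 higher and 93 lower and Z-138 had 104 lower. Without Z-138, JVM-13 had 200 higher and 102 lower and JVM-2 had 85 lower. Without Jeko-1, Mino had 167 higher and 256 lower and Rec-1 had 395 higher and 222 lower. Without Rec-1, Jeko-1 had 387 higher and 288 lower and Mino had 153 higher. Without Mino, Jeko-1 had 333 lower. Background correction by normexp lowered most counts, to between 52 (JVM-13) and 141 (JVM-2) higher and between 22 (Z-138) and 95 (Jeko-1) lower. Restricting the genes to those above background on every array left between 20 (JVM-13) and 66 (Jeko-1) higher. Spike-in scaling turned the balance of calls from 67.2% higher to 9.05% in JVM-13, from 67.5% to 43.1% in Rec-1, from 57.2% to 87.0% in Jeko-1, from 42.4% to 63.7% in Mino, from 66.5% to 81.7% in Z-138 and from 80.8% to 91.3% in JVM-2, and normexp moved it to 61.0% in Mino and 76.8% in Z-138.

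In Rec-1, many but not all genes of antigen presentation were below all other lines, with IFI30, RFX5, ERAP1, CTSS and PSMB10 near the median of the others (-0.22 to 0.26). HLA-DPA1 was 1131-fold lower than in the next lowest line, HLA-DMB 333-fold, HLA-DRB1 70.0-fold, the pseudogene HLA-DPB2 49.3-fold, HLA-DOA 46.2-fold and HLA-DMA 25.7-fold. HLA-DRA and HLA-DPB1 were not well above background in Rec-1 and were at least 1064-fold and at least 970-fold lower, although 1 of the 4 other HLA-DPB1 probes went the other way. CIITA, the master regulator of class II genes, was 19.7-fold lower. Class I genes were lower too, with HLA-F 25.1-fold, HLA-C 6.14-fold, ERAP2 5.26-fold, HLA-E 5.02-fold and HLA-B 4.92-fold. GSTP1, a glutathione transferase, was 744-fold lower, PON2 at least 54.7-fold, the memory B cell marker CD27 43.4-fold, the antiviral OAS2 41.4-fold and TCL1A 25.9-fold. BCL2L2, P2RY8, FCGR2B and XAF1 were between 4.28-fold and 7.41-fold lower. Highest relative to the other lines were the collagenase MMP1 (209-fold), PHEX (169-fold), the Fc receptor-like FCRL3 (165-fold), the drug efflux pump ABCB1 (123-fold) and CA8 (92.9-fold). Rec-1 also exceeded the others in CD3D (41.5-fold), NOTCH3 (39.6-fold), the Notch target HES4 (12.0-fold), the complement receptor CR2 (7.34-fold), the NF-kB subunit REL (5.97-fold), FCRL5 (5.41-fold), FCRL2 (5.17-fold) and the cell death factor BCL2L11 (4.17-fold). Spike-in scaling put REL (2.76-fold), FCRL5 (2.92-fold), FCRL2 (2.39-fold), BCL2L11 (1.93-fold) and FCGR2B (3.22-fold) under 4-fold, and normexp XAF1 (2.13-fold) and FCGR2B (3.98-fold).

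In Jeko-1, genes of several lists were lower than in all other lines, among them NF-kB targets, EBV-induced genes and homing genes. TNF was 72.7-fold below the next lowest line, the cytokine subunit EBI3 48.8-fold, CCL3 21.9-fold, CCL5 21.5-fold and IL21R 37.0-fold, beside PLD6 (70.9-fold) and the histone gene H4C5 (55.6-fold). In all, 32 members of the fixed lists were at least 4-fold lower in Jeko-1. They included CXCR3 (at least 31.1-fold), ICAM1 (8.59-fold), CCL4 (7.10-fold), CD44 (6.22-fold), CCR7 (6.10-fold), TNFAIP3 (5.62-fold), NFKBIA (5.61-fold) and CD40 (4.29-fold). Others were the plasma cell genes PRDM1 (6.51-fold), SLAMF7 (5.08-fold) and XBP1 (4.99-fold), the cell death gene BBC3 (6.96-fold), VEGFA (5.27-fold), PIM2 (4.20-fold) and ALDOC (4.19-fold). ITGB2 (18.9-fold) and LAT2 (5.02-fold) each had a probe that went the other way, and averaging probes gave 2.39-fold and 1.83-fold for them. Higher in Jeko-1 were TCL1B (198-fold), CDHR3 (193-fold), MAGEB2 (143-fold), RHOXF2 (143-fold) and RPRML (142-fold). RHOXF2 and H4C5 have close copies that a probe does not always separate. The recombinase RAG1 was at least 24.7-fold higher and VPREB1, a surrogate light chain gene of precursor B cells, 22.6-fold. CD247 was 60.3-fold higher by its brighter probe, while its other probe went the other way. CTAG2 was 16.8-fold, KLRB1 at least 12.5-fold, DDX43 9.37-fold, the kinetochore motor CENPE 6.05-fold and BACH2 4.27-fold higher. Under spike-in scaling 18 of the 36 genes named as lower fell under 4-fold, among them CCL4 (1.91-fold), PRDM1 (3.01-fold), SLAMF7 (2.35-fold), XBP1 (2.31-fold), BBC3 (3.22-fold), VEGFA (2.44-fold), PIM2 (1.60-fold), ALDOC (1.37-fold), NFKBIA (2.60-fold), CCR7 (2.88-fold) and CD40 (2.38-fold). BACH2 was at 2.94-fold when probes were averaged.

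In JVM-2, the hormone gene PRL was 543-fold above the next highest line, and several cancer-testis antigens, which are normally limited to germ cells, stood out. These were VCX2 (154-fold), MAGEA2B (149-fold), MAGEA12 (99.7-fold), MAGEA1 (66.6-fold), MAGEC2 (49.6-fold), MAGEC1 (39.8-fold), MAGEA10 (at least 9.58-fold) and MAGEA4 (4.76-fold). VCX2 and MAGEA2B have near-identical copies that a probe does not always separate. TMEM119 (68.2-fold), S100A8 (at least 23.9-fold), the interferon-induced IFI27 (10.3-fold), KLRD1 (7.85-fold), TRAT1 (at least 5.22-fold) and the immunoglobulin joining chain JCHAIN (4.17-fold) were also higher. CXCR4 was 139-fold lower than in any other line. FAM24B (37.0-fold), SYTL1 (20.3-fold), AIF1 (17.6-fold), LFNG (14.1-fold) and the serine synthesis gene PSAT1 (13.3-fold) followed, of which FAM24B, AIF1 and LFNG each had a probe going the other way. Normexp put TRAT1 at 2.18-fold, MAGEA4 at 3.56-fold and MAGEA10 at 3.76-fold, spike-in scaling put JCHAIN at 2.72-fold, and averaging probes put LFNG at 3.77-fold.

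In Mino, the largest excesses were in CRIP2 (140-fold), XK (61.2-fold), RARRES2 (58.4-fold), CARNS1 (31.6-fold) and IGFBP2 (31.3-fold). CAV1 was 21.6-fold, CD5 11.4-fold, CD9 7.32-fold, FARP1 5.72-fold, PRF1 5.30-fold and PIK3CG 4.76-fold higher, and the CDK inhibitor CDKN2B at least 4.97-fold (2.30-fold under normexp). The nuclear body protein gene SP140, mutated in some mantle cell lymphomas, was not well above background in Mino, at least 126-fold lower than in any other line. CYB5A (113-fold), SCRN1 (101-fold), RNA5-8SN5 (99.6-fold), KLHL29 (56.2-fold) and DUSP23 (48.4-fold) were lower, with a second KLHL29 probe opposed. RNA5-8SN5 is a ribosomal RNA, and whether its value reflects expression was not tested. The migration receptor GPR183 was 31.5-fold lower, SOX4 at least 27.6-fold, LMO2 at least 13.8-fold, HSPA1A at least 10.66-fold and S1PR2 8.74-fold. Normexp put LMO2 at 3.14-fold, HSPA1A at 2.58-fold and PRF1 at 3.59-fold, and averaging probes put FARP1 at 3.06-fold.

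In Z-138, TPD52L1 (246-fold), SEPTIN10 (79.9-fold), NETO1 (77.1-fold), the hypoxia factor EPAS1 (61.0-fold) and the basement membrane gene NID1 (52.5-fold) were higher. HDGFL3, part of the SOX11-associated list, was at least 72.7-fold lower. SLC41A1 (27.3-fold), IGLL1 (26.2-fold, with a second probe opposed), TMT1A (20.9-fold), ZNF629 (20.1-fold) and ATP2B4 (18.4-fold) were also lower. JVM-13 had higher FAM30A (107-fold), PDE1C (52.2-fold), UBL4B (31.2-fold), LY6S-AS1 (29.7-fold), the sulfatase SULF1 (25.97-fold) and S100A9 (4.78-fold). In JVM-13, CBS, which makes cystathionine, was 59.5-fold lower. ARHGAP15 (19.0-fold), VGF (15.3-fold), ZNF395 (14.96-fold), MIAT (14.2-fold) and CNR1 (at least 5.82-fold) were lower as well. For MIAT 2 of 13 other probes were opposed, and averaging probes gave 2.30-fold. CNR1 was at 2.22-fold under normexp, and S100A9 at 3.75-fold there and 2.03-fold under spike-in scaling.

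Gene lists fixed before the data were examined were then compared. For each list and line the median over members of the difference between the line and the median of the other 5 lines was set against 10000 random lists of the same size and mean level. Of 174 combinations, 89 lay outside the central 95% of random lists, where 8.7 would do so if members were independent. Members of a list vary together, so the percentiles describe these arrays and are no test. Values without a line are given for these lists where, with that line left out, the list no longer stood apart. Spike-in scaling moved the median of all genes by -1.16 in JVM-13, 0.74 in Jeko-1, 0.52 in Mino, -0.37 in Rec-1 and 0.13 in JVM-2, and quantile normalization moved it by 0.11 in Mino, and the authors' values by -0.14 (JVM-13) to 0.04 (Mino). Random lists carry the same movement, so each percentile is relative to it. The authors' values are centred, so their random lists were not matched on expression level. A call lost with them alone may reflect that matching.

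Interferon-stimulated genes gave some of the largest shifts. Their median was 3.098 higher in JVM-2, 2.65 in Z-138 and 1.72 in JVM-13, and it was -3.96 in Rec-1, -2.95 in Jeko-1 and -1.73 in Mino. In JVM-2, 21 of 24 members were at least 2-fold higher, and in Rec-1 23 of 24 were at least 2-fold lower. IFI44L was at 4.62 in JVM-2 and not well above background in Rec-1. Within the slide the shifts were 4.44 in JVM-2, 3.01 in JVM-13, -3.01 in Jeko-1 and -4.01 in Rec-1, and Z-138 exceeded Mino by 2.68. Genes that EBV induces in lymphoblastoid cells (13 of 29 members also in another list) had shifts of 1.48 in JVM-13, 1.36 in Z-138, 1.15 in JVM-2, -1.43 in Mino and -4.36 in Jeko-1, where 28 of 29 members were at least 2-fold lower. SLAMF1 was at 5.35 in JVM-13, 4.96 in Z-138 and 4.91 in JVM-2 and between -3.30 and -2.48 in the other lines, and TNFRSF8 (CD30) ran from -3.13 in Jeko-1 to 6.08 in JVM-13. Within the slide the EBV list was at 1.68 in JVM-13, 1.15 in JVM-2 and -4.36 in Jeko-1, and Z-138 exceeded Mino by 2.54. Rec-1 was at -0.70 (-0.85 within the slide), a shift that became 0.03 without Z-138, 0.03 without JVM-13 and 0.07 without JVM-2.

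Canonical NF-kB targets (12 of 23 members also in another list) were shifted by 1.11 in Z-138, 0.97 in JVM-13 and 0.66 in JVM-2, against -2.25 in Jeko-1 and -0.69 in Mino. In Jeko-1, 20 of 23 members were at least 2-fold lower. Among them were CCL3 (1.42, against 8.998 in JVM-2) and TNFAIP2 (-1.32, against 6.00 in JVM-13), which are also in the EBV-induced list. Within the slide the values were 1.29, 0.73 and -2.25 in JVM-13, JVM-2 and Jeko-1, and Z-138 exceeded Mino by 1.19. Rec-1 was at -0.39, which turned to 0.18 without Z-138 and 0.17 without JVM-13 and was -0.06 without JVM-2, -0.09 within the slide and no longer apart with the authors' values (-0.29) or spike-in scaling (-0.70). Homing and adhesion genes were shifted by 1.13 in Z-138, 1.13 in JVM-13, 0.83 in JVM-2, -2.08 in Jeko-1 and -1.10 in Rec-1 (0.97 above Mino for Z-138, and 1.68, 0.73, -2.08 and -0.72 within slide 2). For JVM-2 this was 0.12, no longer apart from random lists, over members above background on every array. In Mino the shift was -0.44, but 0.16 without Z-138, 0.01 without JVM-13, -0.20 without Rec-1 and -0.23 over members above background on every array. The alternative NF-kB pathway (7 of 12 members also in another list) stood apart in Z-138 (0.59), JVM-2 (-0.45) and Mino (-0.39). None of these held throughout: for Z-138 the value was 0.35 both without JVM-2 and without Mino, for Mino -0.18 without JVM-13, and for JVM-2 between -0.36 and -0.12 without Z-138, JVM-13, Jeko-1 or Rec-1 in turn. JVM-2 was also not apart with the authors' values (-0.42) or spike-in scaling (-0.08), nor Mino under spike-in scaling (percentile 3.86).

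MHC class II genes had a shift of -5.44 in Rec-1, the same within the slide, with 9 of 13 members at least 2-fold lower, and of 0.96 in Z-138 (0.57 above Mino). In JVM-13 the shift was -0.54, but -0.38 within the slide and -0.63 with the authors' values, neither apart from random lists. MHC class I and antigen processing genes were at -2.93 in Rec-1 (12 of 15 members lower), -1.17 in Jeko-1, 0.85 in JVM-2 and 0.80 in Z-138 (-3.18, -1.34 and 1.17 within slide 2, and 0.80 above Mino). In JVM-13 their shift was 0.78 (1.34 within the slide), but 0.43 without Jeko-1 and 0.44 without Rec-1. In Mino it was -0.61, but 0.01 without Z-138, -0.03 without JVM-13 and 0.01 without JVM-2. Under spike-in scaling, which moved all genes of these arrays, the class I values in JVM-13 (-0.90) and Mino (0.47) lay at percentiles 96.2 and 13.2 of random lists, no longer apart.

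Growth arrest and DNA damage genes were shifted by 1.45 in JVM-13 and 1.01 in JVM-2, and by -1.88 in Jeko-1 and -0.94 in Rec-1 (1.31, 1.01, -2.19 and -1.17 within the slide). In JVM-13, 14 of 21 members were at least 2-fold higher, and in Jeko-1 17 of 21 were at least 2-fold lower. GDF15 was between 3.18 and 3.77 in Z-138, JVM-13 and JVM-2 and between -2.67 and -2.29 in the other lines, and FAS ran from -4.23 in Jeko-1 to 2.62 in JVM-13. In Mino the shift was -0.75, but -0.28 without JVM-2. In Z-138 it was 0.47 (1.01 above Mino), but 0.04 without Mino, -0.03 without Jeko-1 and 0.04 without Rec-1. Proliferation genes were highest in Jeko-1 (1.24, 17 of 26 members at least 2-fold higher, 1.24 within the slide), with CENPE at 2.84 and CENPF at 5.56. They were at 0.47 in Mino, -0.84 in Z-138 and -0.54 in JVM-13 (-0.66 within the slide), with Mino 1.02 above Z-138.

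Lists of B cell stage separated the lines. Mature B cell genes were at 1.41 in Mino, 0.89 in Rec-1, -0.92 in JVM-2 and -0.58 in Z-138 (0.89 and -1.06 within slide 2, and Mino 1.67 above Z-138). The member CD200 went against the list in Z-138 and Rec-1. CD200 was at 3.02 in Z-138 and not well above background in Jeko-1 and Rec-1. The list was at 0.44 in Jeko-1, but between 0.12 and 0.43 without Z-138, JVM-13, JVM-2 or Mino in turn, and not apart within the slide (0.47), over members above background on every array (0.32), with probes averaged (0.43) or with the authors' values (0.55). Plasma cell genes were at 1.84 in JVM-2, 0.86 in JVM-13, -2.08 in Jeko-1 and -1.60 in Rec-1 (2.17, 1.40, -2.27 and -1.78 within the slide). SLAMF7 was at 6.16 in JVM-2 and -3.90 in Jeko-1, and SDC1 (CD138) at 4.89 and -2.16. Precursor B cell genes were at 1.49 in Jeko-1 (1.33 within the slide), 0.65 in Mino and -0.79 in Z-138, where LEF1 was at -5.44 against 4.12 in Mino. Within slide 1 Mino exceeded Z-138 in this list by 0.29. Averaging probes left Mino at 0.41, and normexp and the authors' values left Z-138 at -0.21 and -0.31, none apart from random lists. Germinal centre genes stood apart in Jeko-1 (0.91), JVM-13 (0.76) and Z-138 (-0.70), but within slide 2 the first of these fell to 0.18 and JVM-13 to 0.38, and Z-138 was at -0.10 (-0.095) against Mino. Without Mino the Jeko-1 shift was 0.68 and without Rec-1 0.76, and Z-138 was at -0.40 without JVM-13 and without JVM-2. The calls were also lost under normexp in Jeko-1 (0.52) and JVM-13 (0.41), over members above background on every array (0.91 and 0.15), with the authors' values in Jeko-1 (0.74) and under spike-in scaling in Z-138 (-0.35).

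The SOX11-associated list was at 1.12 in Mino (8 of 13 members at least 2-fold higher), 0.82 in JVM-2, -0.91 in JVM-13 and -0.89 in Z-138, while Jeko-1 (0.21) and Rec-1 (-0.39) did not stand apart. Mino exceeded Z-138 by 1.46, and within slide 2 JVM-2 was at 0.84 and JVM-13 at -0.51, the latter no longer apart. JVM-2 fell to 0.28 without JVM-13 and 0.29 without Rec-1, and Z-138 to -0.49 without JVM-2. Over members above background on every array Z-138 was at -0.30 and JVM-2 at 0.34, neither apart, and JVM-2 was not apart under spike-in scaling (0.47). Notch targets were at 2.33 in Rec-1 (9 of 12 members higher, 2.14 within the slide) and -0.99 in JVM-2. HES4 was at 7.41 in Rec-1 and 3.81 in Z-138 and at or below -1.98 in the other lines, and DTX1 at 4.14 in Mino and not well above background in JVM-13 and JVM-2. Mino was at -0.76 for Notch targets (-0.19 against Z-138), but -0.28 without Jeko-1, -0.24 without Rec-1, -0.30 under normexp and 0.13 over members above background on every array. Cancer-testis antigens were at 3.001 in JVM-2 (10 of 14 members higher, 2.72 within the slide). Their shifts in Rec-1 (0.79, 0.03 within the slide), Mino (-0.84) and Z-138 (-0.77) did not hold (Mino was at -0.07 against Z-138), with Rec-1 between 0.35 and 0.71 without Z-138, JVM-2, Mino or Jeko-1, Mino at -0.52 without JVM-2 and -0.66 without Rec-1, and Z-138 at -0.53 without either of them and 0.07 above Mino. All 3 were also lost under normexp (0.28, -0.15 and -0.21) and with the authors' values (0.46, -0.45 and -0.24). Over members above background on every array Rec-1 (0.50) and Z-138 (-0.23) were not apart, nor were Z-138 (-0.37) and Mino (percentile 8.42) under spike-in scaling or Mino under median scaling (-0.72).

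MYC and nucleolar genes were at 0.68 in Rec-1, -0.77 in JVM-13 and -0.63 in JVM-2 (0.93, -0.77 and -0.73 within the slide), with PPAN at 2.02 in Rec-1 and -0.37 in JVM-2. The unfolded protein and amino acid response list was at 1.02 in JVM-13 (10 of 19 members higher) and -1.74 in Jeko-1 (12 lower), with 1.09 and -1.74 within the slide. SESN2 was at 3.54 in JVM-13 and -2.12 in Jeko-1. Its smaller shifts in Z-138 (0.33), JVM-2 (0.31) and Mino (-0.35) were of similar size with the authors' values (0.36, 0.32 and -0.34) but no longer apart from random lists (percentiles 94.6, 94.3 and 8.91). Those random lists were not matched on expression level. Within the slides Z-138 exceeded Mino by 0.64 and JVM-2 was at 0.44. JVM-2 was at 0.20 without Mino and 0.13 without Jeko-1 and Mino at -0.12 without Z-138 and -0.14 without JVM-2. The BCL2 family was at -1.14 in Jeko-1 (-0.85 within the slide), where 11 of 20 members were lower and BBC3 was at 0.36 against 5.38 in JVM-13, while HRK was highest there at 2.58. The BCL2 family shift of 0.24 in Z-138 was -0.04 without Jeko-1, 0.22 without JVM-13, 0.11 without Mino, 0.02 without Rec-1 and -0.01 against Mino, and among the other alternatives it stood apart only under median scaling and over members above background on every array. Heat shock and immediate early genes were at 0.94 in Mino (0.41 above Z-138) and -0.60 in JVM-2 (-0.58 within the slide, but -0.40 and no longer apart without JVM-13).

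Smaller shifts were found for the hypoxia and glycolysis list in Z-138 (0.29, but 0.17 against Mino and not apart with the authors' values at 0.33) and Rec-1 (-0.41, but no longer apart within the slide at -0.27, without Z-138 at -0.28 or without Mino at -0.29), for genes mutated in this lymphoma in Mino (0.51 and 0.40 against Z-138, but 0.31 without JVM-13 and without JVM-2, and between 0.36 and 0.44 and not apart under quantile normalization, normexp, the authors' values and over members above background on every array) and for therapy targets in Z-138 (-0.36 and -0.61 against Mino, but no longer apart without Mino at -0.29 or with the authors' values at -0.32). Single therapy targets still varied widely. ROR1 was at 1.73 in Jeko-1, 1.27 in Rec-1 and 0.46 in Mino and not well above background in the other 3 lines, and CD274 (PD-L1) was near 1.95 in Z-138, JVM-13 and JVM-2 and at most -4.35 elsewhere. B cell receptor signalling genes stood apart in no line, with shifts between -0.16 (JVM-2) and 0.35 (Mino), and neither did G1 cyclins, CDKs and their inhibitors (-0.28 in JVM-13 to 0.52 in Jeko-1). CDK6 within that list was at 4.19 in Z-138, 3.27 in JVM-2 and 3.13 in JVM-13 and not well above background in Mino or Jeko-1. Of the marker lists of other cell types, only T cell markers stood apart, in a single line. They had a shift of 0.77 in JVM-13, which was -0.00 within the slide and between 0.11 and 0.55 when other lines were left out in turn. It was 0.14 under normexp, 0.38 with probes averaged and -0.07 over markers above background on every array, and spike-in scaling left it at percentile 94.5. Myeloid markers ran from -0.90 in Jeko-1 to 0.42 in Z-138, NK cell markers from -0.86 in Mino to 1.05 in JVM-13, and erythroid and stromal markers from -0.70 in Jeko-1 to 0.60 in JVM-13, all within the central 95% of random lists.

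**Figure D3:**
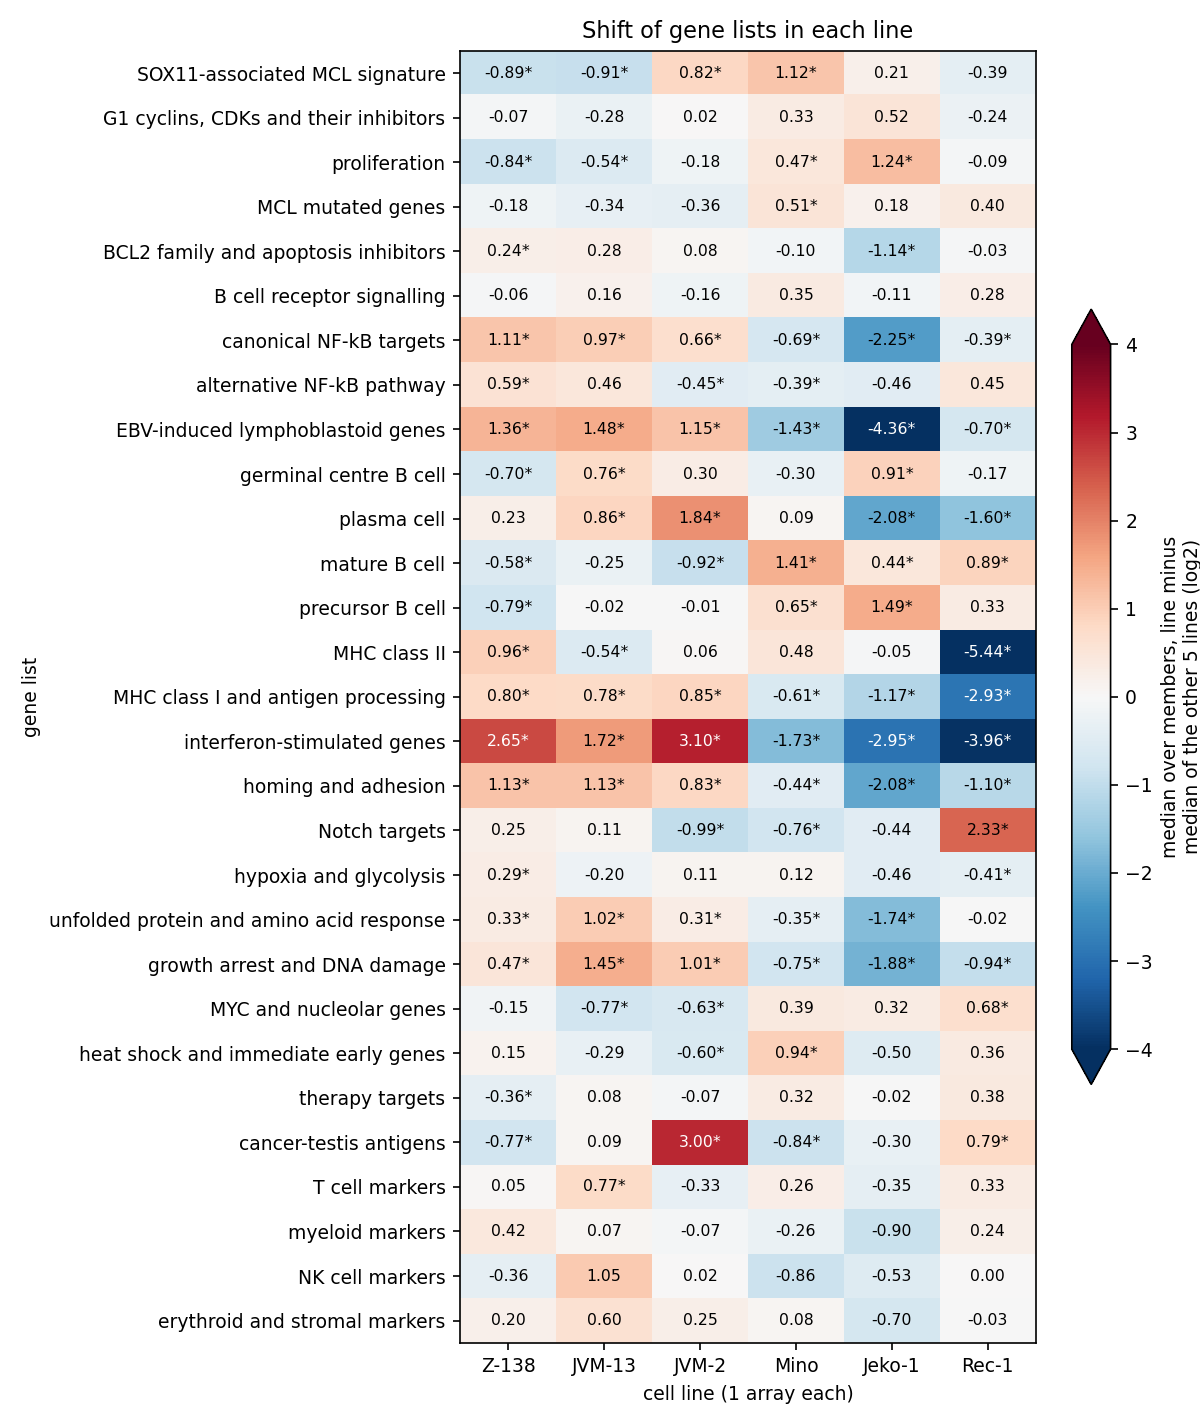
Median over the members of each gene list (rows) of the level in a line minus the median of the other 5 lines (log2), for the 6 lines (columns, 1 array each), with an asterisk where the value lies outside the central 95% of 10000 random lists. Interferon-stimulated genes run from -3.96 in Rec-1 to 3.098 in JVM-2, and MHC class II is at -5.44 in Rec-1.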

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

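The tests that weigh explanations in this part were all chosen after the results were seen. Over 52 values or list medians compared across the 6 lines, 5 had a line so far from its nearest neighbour that the gap exceeded Dixon's 95% critical value for 6 samples, where chance gives about 1 in 20. CXCR4 was at -4.25 in JVM-2, with the nearest line at 2.86. The median level of precursor B cell genes was 0.00 (0.004) in Jeko-1, against -4.17 in the nearest line. The shift of that list in Jeko-1, taken member by member, was smaller at 1.49, with 5 of 10 members at least 2-fold higher. The median level of cancer-testis antigens was -0.37 in JVM-2, against -4.21. The median level of myeloid markers was -3.83 in Jeko-1, against -2.88. Against random lists matched on mean level they did not stand apart there (percentile 3.53), and Jeko-1 had the lowest array floor (-6.29). The median level of MHC class II genes was -1.69 in Rec-1, against 3.35.

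Low MHC genes in Rec-1 were weighed against 2 technical causes. HLA genes vary between people, so a probe might miss a variant. List members other than the classical HLA genes were also lower, by a median of -2.79 (-2.785), and 14 of 21 by at least 2-fold. That set still held HLA-DMA (-5.44), HLA-DMB (-9.11), HLA-DOA (-7.235), HLA-DOB (-1.67), HLA-E (-4.645) and HLA-F (-6.86). Its median therefore does not describe genes outside HLA, which were mixed. At least 2-fold lower among these were CIITA (-5.11), NLRC5 (-3.39), B2M (-3.05), ERAP2 (-2.93), PSMB8 (-2.92), TAP1 (-2.79), PSMB9 (-2.52) and TAP2 (-1.02). Within 2-fold of the other lines were TAPBP (-0.965), CD74 (-0.949), PSMB10 (-0.22), CTSS (-0.17), ERAP1 (-0.04), RFX5 (-0.00) and IFI30 (0.26). Differences in array scale were too small to give this deficit. The 6 scalings moved the median of all Rec-1 genes by -0.37 at most, so they could hardly have closed it. The smallest deficit under them was -2.83 (28 genes, largest -3.58). These values speak against array scale. They speak against mismatch at HLA probes as the whole cause, because several genes outside HLA were lower too. For the HLA genes themselves mismatch was not tested. Reduced expression of MHC genes in Rec-1 may be biological, as a hypothesis found and tested on the same data.

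A signal also appeared in control probes that no comparison used. Of 96 probes for ERCC control transcripts, which no label says were added, 20 were above background in Z-138, 13 in JVM-13, 12 in JVM-2, 26 in Mino, 23 in Jeko-1 and 9 in Rec-1.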

How the results depend on the processing

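Spike-in scaling was the alternative chosen after seeing the data, and the others were planned. The number of list shifts standing apart stayed between 78 and 91 under every alternative that could be computed for it, against 89. Of the 89 shifts, 59 stood apart on the same side of random lists under every alternative except leaving out a line. This held for 62 whichever line was left out, and for 54 under all of these. For the 59 and 54, losses with the authors' values were counted, although random lists there were not matched on expression level. Of 175 named gaps of at least 4-fold, none reversed, 32 fell below 4-fold under spike-in scaling and 40 under at least 1 of the others, and the smallest was 0.45. Median scaling, quantile normalization, the authors' values and averaging probes left every count of genes within 1.5 times. The slide 1 lines have no values when only slide 2 is used. No paired analysis was possible because each line has 1 array. Signal over background limits genes that are dim: Rec-1 and JVM-2 had the fewest probes above background (27899 and 29081), and a fold against a dim probe is a bound.

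Counts under normexp, which adds an offset that shrinks differences at low signal, moved by over 1.5 times as follows. Higher genes numbered 73 in Z-138, 52 in JVM-13, 141 in JVM-2, 1.4e2 (rounded) in Jeko-1 and 129 in Rec-1. Lower genes numbered 22 in Z-138, 25 in JVM-13, 29 in JVM-2, 39 in Mino, 95 in Jeko-1 and 80 in Rec-1. Genes 4-fold apart numbered 768 for Z-138/JVM-13, 889 for Z-138/JVM-2, 1419 for Z-138/Mino, 2087 for Z-138/Jeko-1, 1574 for Z-138/Rec-1, 701 for JVM-13/JVM-2, 1453 for JVM-13/Mino, 1682 for JVM-13/Rec-1, 1553 for JVM-2/Mino, 2038 for JVM-2/Jeko-1, 1675 for JVM-2/Rec-1, 1076 for Mino/Jeko-1, 1095 for Mino/Rec-1 and 1294 for Jeko-1/Rec-1. Genes higher in both lines of a pair numbered 36 in the JVM pair, 2 in the slide 1 pair and 37 in the highest other pair. Genes lower in both lines of a pair numbered 12 in the JVM pair, 2 in the slide 1 pair and 53 in the highest other pair.

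Over genes above background on all arrays, fewer genes could be counted. Higher genes numbered 30 in Z-138, 20 in JVM-13, 29 in JVM-2, 29 in Mino, 66 in Jeko-1 and 58 in Rec-1. Lower genes numbered 32 in JVM-13 and 57 in Mino. Genes 4-fold apart numbered 622 for Z-138/JVM-13, 633 for Z-138/JVM-2, 1125 for Z-138/Mino, 1727 for Z-138/Jeko-1, 1240 for Z-138/Rec-1, 480 for JVM-13/JVM-2, 1183 for JVM-13/Mino, 2055 for JVM-13/Jeko-1, 1335 for JVM-13/Rec-1, 1159 for JVM-2/Mino, 1668 for JVM-2/Jeko-1, 1278 for JVM-2/Rec-1, 1042 for Mino/Jeko-1, 949 for Mino/Rec-1 and 1189 for Jeko-1/Rec-1. Genes higher in both lines of a pair numbered 15 in the JVM pair and 21 in the highest other pair. Genes lower in both lines of a pair numbered 11 in the JVM pair, 5 in the slide 1 pair and 49 in the highest other pair. Without a filter, where dim probes enter the counts, the values were these. Lower genes numbered 173 in Mino. Genes higher in both lines of a pair numbered 7 in the slide 1 pair. Genes lower in both lines of a pair numbered 36 in the JVM pair and 33 in the slide 1 pair. With only the 4 lines of slide 2 there were fewer lines to exceed. Higher genes numbered 238 in JVM-13, 383 in Jeko-1 and 383 in Rec-1. Lower genes numbered 152 in JVM-13, 114 in JVM-2, 405 in Jeko-1 and 196 in Rec-1. Genes higher in both lines of a pair numbered 523 in the JVM pair and 320 in the highest other pair. Genes lower in both lines of a pair numbered 320 in the JVM pair and 523 in the highest other pair. Leaving out each line in turn has the same effect and gave 140 to 239 higher and 85 to 122 lower in Z-138, 130 to 232 higher and 63 to 102 lower in JVM-13, 237 to 337 higher and 64 to 85 lower in JVM-2, 95 to 167 higher and 127 to 256 lower in Mino, 241 to 387 higher and 183 to 333 lower in Jeko-1 and 274 to 395 higher and 131 to 222 lower in Rec-1.

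Spike-in scaling moves all genes of an array alike, with medians of -1.16 in JVM-13, -0.37 in Rec-1, 0.08 in Z-138, 0.13 in JVM-2, 0.52 in Mino and 0.74 in Jeko-1, so the counts below moved by construction. Higher genes numbered 196 in Z-138, 36 in JVM-13, 135 in Mino, 470 in Jeko-1 and 132 in Rec-1. Lower genes numbered 362 in JVM-13, 29 in JVM-2 and 70 in Jeko-1. Genes 4-fold apart numbered 3132 for Z-138/JVM-13, 2713 for JVM-13/JVM-2, 7181 for JVM-13/Mino, 8599 for JVM-13/Jeko-1 and 3610 for Jeko-1/Rec-1. Genes higher in both lines of a pair numbered 37 in the JVM pair, 10 in the slide 1 pair and 170 in the highest other pair. Genes lower in both lines of a pair numbered 33 in the JVM pair, 9 in the slide 1 pair and 68 in the highest other pair.

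Some list shifts changed sign and no longer stood apart, and outside spike-in scaling and left-out lines (fewer comparators) the cause was not tested. Shifts that changed sign but stood apart on the same side of random lists are not given here. Over genes above background on all arrays, Notch targets in Mino were at 0.132 and T cell markers in JVM-13 at -0.066, and within slide 2 the latter were at -0.001. Under spike-in scaling, where the sign follows the movement of all genes, the alternative NF-kB pathway in Mino was at 0.262, MHC class I at -0.899 in JVM-13 and 0.467 in Mino, cancer-testis antigens in Mino at 0.031 and T cell markers in JVM-13 at -0.832. Against random lists, which move alike, these lay at percentiles 3.86, 96.2, 13.2, 8.42 and 94.5, on the side of the value without spike-in scaling but not apart. Without Z-138, canonical NF-kB targets in Rec-1 were at 0.18, EBV-induced genes in Rec-1 at 0.027, MHC class I in Mino at 0.011 and homing genes in Mino at 0.164. Without JVM-13, these were 0.165 for NF-kB and 0.027 for EBV-induced genes in Rec-1 and 0.007 for homing genes in Mino. Without JVM-2, EBV-induced genes in Rec-1 were at 0.074 and MHC class I in Mino at 0.013. Without Jeko-1, the BCL2 family in Z-138 was at -0.044 and growth arrest and DNA damage genes in Z-138 at -0.031. Over all left-out lines the ranges were -0.504 to 0.18 (NF-kB) and -0.831 to 0.074 (EBV-induced) in Rec-1, -0.621 to 0.013 (MHC class I) and -0.395 to 0.164 (homing) in Mino, and -0.044 to 0.337 (BCL2 family) and -0.031 to 0.787 (growth arrest and DNA damage genes) in Z-138.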

Other observations

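The tests that weigh explanations in this part were all chosen after the results were seen, as were the genes. Several list members shared the split of the lines by SOX11, and how many genes share it was not counted. The EBV-induced list split the lines alike. It was at 1.36 in Z-138, 1.48 in JVM-13 and 1.15 in JVM-2, against -1.43 in Mino, -4.36 in Jeko-1 and -0.70 in Rec-1. A link of the genes below to SOX11 therefore cannot be told apart from a link to that list or to the likeness of Z-138 to the JVM lines. ROR1, a receptor targeted by therapy, and TLR2, an innate receptor, were above background in Mino (0.46 and -0.09), Jeko-1 (1.73 and 0.09) and Rec-1 (1.27 and -1.31) and in none of the other 3 lines. NOTCH2 was at 2.74, 3.35 and 4.34 in Mino, Jeko-1 and Rec-1 and between -3.41 and -0.64 in the other lines. CDKN2C, an inhibitor of CDK4 and CDK6, was at 3.72, 3.78 and 4.75 there and between -2.90 and 0.96 elsewhere. CDK6 went the other way, from 3.13 in JVM-13 to 4.19 in Z-138, against -3.97 in Rec-1 and no signal above background in Mino and Jeko-1. The split did not always follow the level of SOX11. NOTCH2 and CDKN2C were highest in Rec-1, where SOX11 was lowest of its 3 lines (1.65), although TLR2 was lowest there too. The SOX11-associated list was at 0.82 in JVM-2 and did not stand apart in Jeko-1 or Rec-1.

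The Z-138 array resembled the JVM arrays. A slide or scan effect is argued against, since Z-138 correlated at 0.8886 with Mino on its own slide and at 0.9375 with JVM-13 on the other. JVM RNA mixed into the Z-138 sample is argued against as the whole cause. Among 273 genes high in JVM-2 the tenth percentile of the Z-138 level was 1.26% (1.257) of the JVM-2 level. EBV-induced genes high in JVM-2 reached a median of 115% in Z-138, more than JVM-2 RNA alone could give. Among 196 genes high in JVM-13 the tenth percentile was 2.58% (2.584) of the JVM-13 level, against a median of 89.3% for EBV-induced genes. A smaller admixture was not tested. A culture other than the label says could also give this pattern. SOX11 was not well above background in Z-138, JVM-13 or JVM-2, and the EBV-induced list was at 1.36, 1.48 and 1.15 in these lines. Z-138 was 1384 genes apart from its nearest line. No profile of the line from outside these data was compared, so no value here decides it. A shared biological state is untested.

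CCND1 was low in Jeko-1 and Rec-1. In JVM-13 it was not well above background, and that line was left out of what follows. The 6 scalings moved the median of all genes by at most 0.74 in Jeko-1, 0.52 in Mino and -0.37 in Rec-1. That is too little to close the gap to Mino, which argues against array scale as the cause. The smallest deficit of either line below Mino under them was -4.50 (-4.499, largest -7.91). Transcripts that end before the probe might read as low, and with 1 CCND1 probe on the array, toward the 3′ end, this cannot be told apart from low expression.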
